A study of Mus musculus with 32 samples.

How the data were processed

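RNA from polysome gradients of mouse NIH 3T3 fibroblasts and of NIH 3T3/4E cells, a derivative that ectopically overexpresses the cap-binding translation initiation factor eIF4E, was hybridised to 2-colour arrays of the NIH 15k mouse cDNA collection. Per the labels and the series' design text, the light pool holds gradient fractions 4 to 6 and the heavy pool fractions 7 to 10. Cells were in complete medium (basal) or without serum for 16 h (starved). Every array carried the same reference, poly(A) RNA of NIH 3T3 cells in full medium that was not separated on a gradient. The 32 deposited columns fall into 8 groups of cell line, fraction and serum state, with title numbers that run over 4 columns in each group.

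The authors deposited log ratios of each sample against the common reference, made by competitive 2-colour hybridisation per the labels, and these were taken as log2 values. The log base, the centring and the direction of the ratio (sample over reference or the reverse) are not given in the sources used here, and neither are the scanner, the background correction, the normalization within arrays and any filter on spots. The largest absolute value was 11.3, which excludes a log10 scale for a 2-colour scanner but does not exclude a natural log. The lowest correlation between any 2 columns over all clones was 0.02, and none was below 0, so the columns run the same way. Which sign stands for more RNA in the polysome sample stayed open, so differences are given as coded on the deposited scale, and positive or negative does not mean more or less RNA. Column medians lay between -0.15 and 0.18. The number of arrays limits the precision. Signal over background is not used here.

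The table held 15249 rows, of which 15247 were clones and 2 were controls (3XSSC buffer and Arabidopsis). The files do not pair clone IDs with genes, and 0 of the IDs were found in the mouse RefSeq gene table used here (assembly GRCm38.p6). The gene lists, the check of eIF4E itself, the averages per gene and the cell type markers fixed before the data were examined therefore could not be run. Clones are named by ID only, at most 2 with a positive and 2 with a negative difference in each comparison. They are those with the largest difference among clones with adjusted p under 0.05, or, where none passed, those with the smallest p, given as values. This follows the order of the rule fixed beforehand, which was written for genes.

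The columns of each group turned out to be 2 pairs, title numbers 1 with 2 and 3 with 4. In each of the 16 pairs one column was at or above the other at every clone, with no exception (tolerance 1e-06), and 8.53 to 23.8% of the clones had equal values in both columns. Missing values were shared by both columns of a pair. A pair was therefore taken as an upper and a lower value of 1 sample, such as the higher and the lower of 2 spots or limits around a mean, and the mean of its 2 columns was used as the sample's value. This leaves 16 samples, 2 in each of the 8 groups. The design fixed before the data were examined counted each column as a replicate, and averaging the pairs had been listed as an alternative. The choice between them was made after the columns were seen and before the comparisons were tested. Counts under the earlier design are among the alternatives.

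Clones measured in all 16 samples were kept, 15169 in all, and 78 with a missing value were left out. The filter fixed beforehand and the stricter one that asks for all 32 columns kept the same clones. Each sample was centred on its median, which shifted it by at most 0.052. Differences were tested with limma (version 3.58.1 under R 4.3.3), with 1 fit of 8 group means over the 16 samples, contrasts between them, empirical Bayes moderation and Benjamini-Hochberg adjustment over clones within each contrast. The fit had 8 residual degrees of freedom per clone, and its prior had 6.51. The threshold was an adjusted p of 0.05. The averages of the cell line difference and of the starvation difference over the other factors, and contrasts within each side of the split of the samples by control rows, were added after the data were seen. Sums of squares over all clones were tested by an exact permutation test that relabels 1 factor within the 4 strata of the other factors (1296 relabellings). Correlations between contrasts were computed across clones, from contrasts that share no sample. Clones are not independent replicates, and no p is given for these correlations.

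The fit was tested on simulated data drawn with the spread of the 15169 clones, with 200 clones changed in each of 40 runs. The noise was normal and independent, with the same SD in all samples of a clone and no other difference between groups. Samples of unequal spread and the technical split of the real data were not simulated, so the percentages below hold only under these settings. A first test of 5 runs had exceeded its limit of 10% false calls for the term of all 3 factors, with 3 false among 10 calls, and the number of runs was raised under the same limit. For 4E against NIH 3T3 in the heavy basal fraction, 3.75% of changes of 1 log2 unit, 70.4% of changes of 2 units and 97.3% of changes of 3 units passed the threshold. For heavy against light over 4 states, 75.5% of changes of 1 unit passed. For the cell line by fraction term in basal cells, 0.3% of changes of 1 unit, 15.1% of changes of 2 units and 68.7% of changes of 3 units passed. For cell line by serum in the heavy fraction, 13.9% of changes of 2 units and 68.4% of changes of 3 units passed. For the term of all 3 factors, 3.7% of changes of 3 units passed. False calls made up 4.99%, 5.51%, 5.45%, 5.85% and 8.24% of the calls in these comparisons, in that order.

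The alternatives tried were the replicate number as a block, no centring, quantile normalization, scaling to 1 median absolute deviation, a wider filter on missing values, fits of only the groups compared, robust moderation, array weights, each column as a replicate and leaving out each sample. Those chosen after seeing the data were the higher or the lower column alone, only clones with unequal columns in every sample, removal of plate medians, and a pairing of the heavy with the light sample of 1 state. No array needed its sign turned.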

Results

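The study asked which transcripts change their place on polysomes when eIF4E is overexpressed and when serum is withdrawn, in a cell line that eIF4E makes resistant to apoptosis. Ratios against 1 common reference were measured for 15169 cDNA clones in 16 samples, 2 for each combination of cell line, polysome fraction and serum state. The heavy fraction carries transcripts with more ribosomes than the light fraction. The labels do not say that the 2 samples of a group came from separate cultures, so p-values measure the spread between these samples, which can be technical. The 2 columns of a sample correlated across clones at r of 0.86 to 0.95, and where they were unequal their median gap was 0.20 log2 units in the middle sample. The median residual SD between the samples of a group was 0.39 log2 units. Samples of 1 group correlated across clones at r of 0.53 (4E heavy starved) to 0.68 (4E heavy basal), and 10 of the 16 samples were closest to their own replicate. The 2nd sample of 4E heavy starved had the widest spread, with a median absolute deviation of 0.74 and a median r of 0.33 with the other samples. Of the 51 clones named by the rule, 35 had equal values in both columns of at least 1 sample. The median number of such samples was 1 for the named clones and 2 for all clones.

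**Figure D1:**
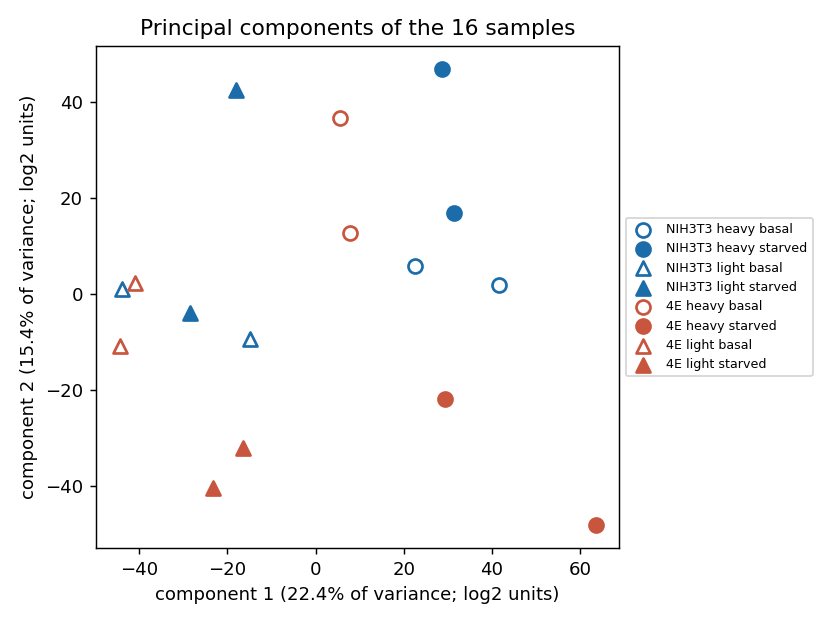
Principal components of the 16 samples (axes in log2 units, with the percent of variance), circles for heavy and triangles for light fractions, filled for starved and open for basal cells, blue for NIH 3T3 and red for NIH 3T3/4E. The 8 heavy samples lie at positive and the 8 light samples at negative values of component 1, which holds 22.4% of the variance.

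The polysome fraction was the largest single term of the design. It took 19.6% of the sum of squares over all clones, 4.28 times the mean square between replicate samples. The two-sided exact permutation p was 0.00154, the smallest that the 1296 relabellings can give, and 0.00463 after Benjamini-Hochberg adjustment over the 3 factors. The cell line took 9.96% (exact permutation p = 0.0108, adjusted 0.0123) and serum 9.69% (exact permutation p = 0.0123, adjusted 0.0123). The cell line by serum term took 12.5%, 2.73 times the replicate mean square. The cell line by fraction term took 3.39% and serum by fraction 3.42%, both below the replicate mean square, and the term of all 3 factors 4.82%.

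**Figure D2:**
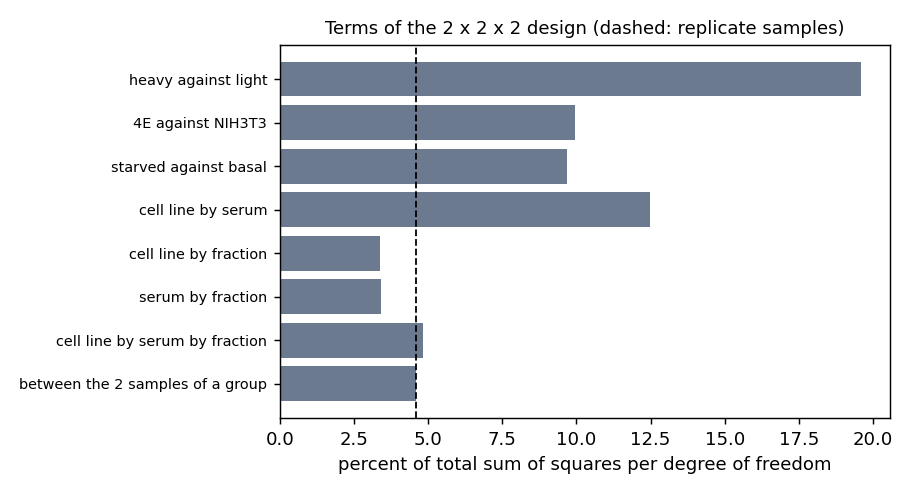
Percent of the total sum of squares per degree of freedom for each term of the design (bars, from 0), with the mean square between the 2 samples of a group as the dashed line. The fraction, cell line by serum, cell line and serum terms lie above the line, at 19.6, 12.5, 9.96 and 9.69%, and the term of all 3 factors, at 4.82%, lies just above it, at 1.05 times the replicate mean square.

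Heavy and light fractions differed at 2743 clones (18.1% of those tested), 1411 with a positive and 1332 with a negative heavy minus light difference, averaged over the 4 states of cell line and serum. Clone H3059E05 had the largest positive difference, from -1.09 ± 0.39 in the light to 1.11 ± 0.45 in the heavy samples (SD, n = 8 each), a difference of 2.20 (SE 0.18, adjusted p = 4.16e-05), with no overlap between the fractions. Clone H3025C05 differed by 2.15 (SE 0.18, adjusted p = 4.16e-05). On the negative side, clone H3155C02 differed by -1.56 (SE 0.23, adjusted p = 0.000433) and clone H3139E06 by -1.55 (SE 0.30, adjusted p = 0.00227), and for both of these the fractions overlapped. Of the 1563 clones that passed in the 8 samples of NIH 3T3 basal and 4E starved cells, 1468 (93.9%) had the same sign in the other 8 samples. Across clones, the heavy minus light differences of separate states correlated at r of 0.43 (4E basal with 4E starved) to 0.60 (NIH 3T3 basal with 4E starved). In single states, 48 clones passed in NIH 3T3 basal (46 positive, 2 negative), 30 in NIH 3T3 starved (29 positive, 1 negative), 0 in 4E basal by limma (1982 at an unadjusted p under 0.05) and 145 in 4E starved (102 positive, 43 negative). Leaving out 1 sample gave 2197 to 2974 clones for the average. The counts of single states moved more, to 19 (without the 2nd light sample) to 71 in NIH 3T3 basal and to 0 (without the 1st heavy sample) to 63 (without the 2nd heavy sample) in NIH 3T3 starved. They moved to 1 to 31 (without the 1st heavy sample) in 4E basal, and to 13 (without the 1st light sample) to 635 (without the 1st heavy sample) in 4E starved.

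In the fit of all 8 groups, NIH 3T3/4E differed from NIH 3T3 in each of the 4 matched pairs, all of which cross the technical split described with the cell line by serum term. In the heavy fraction 68 clones passed in basal cells (28 positive, 40 negative as 4E minus NIH 3T3) and 182 in starved cells (104 positive, 78 negative). In the light fraction 21 passed in basal (9 positive, 12 negative) and 146 in starved cells (89 positive, 57 negative). Scaling to 1 median absolute deviation turned the order of basal and starved counts in the light fraction (116 and 88) but not in the heavy (65 and 87). Array weights turned it in the heavy fraction (162 and 63) but not in the light (67 and 130). Both samples of a group got the same weight, so array weights could not lower 1 sample against its replicate. Fits of only the 2 groups compared, with fewer degrees of freedom, gave 2 (heavy basal), 12 (heavy starved), 0 (light basal) and 0 (light starved) clones. In heavy basal samples, clone H3055A11 differed by 4.13 (SE 0.60, adjusted p = 0.00638) and clone H3073H04 by 3.68 (SE 0.33, adjusted p = 0.000216). Clone H3105C02 differed by -4.04 (SE 0.46, adjusted p = 0.00182) and clone H3076B11 by -3.24 (SE 0.41, adjusted p = 0.00274). In heavy starved samples, clone H3123F12 differed by 4.48 (SE 0.86, adjusted p = 0.0207) and clone H3089A10 by 4.21 (SE 0.42, adjusted p = 0.000205). Clone H3143B04 differed by -4.98 (SE 0.54, adjusted p = 0.000435) and clone H3009C04 by -4.14 (SE 0.37, adjusted p = 8.97e-05). Clone H3105C02 was also among the most negative in light basal samples, at -3.33, and clone H3143B04 in light starved samples, at -4.71. The heavy and light differences went together across clones, with r of 0.40 in basal and 0.52 in starved cells. All 60 clones that passed in both fractions of starved cells had the same sign (1.75 in both by chance), as did all 8 of basal cells. The basal and the starved differences did not, with r of -0.18 in the heavy and -0.07 in the light fraction. Among the 3018 clones with unequal columns in every sample these turned to 0.056 and 0.14. Of the 22 clones that passed in both heavy comparisons 14 had opposite signs. A cell line by serum term larger than the cell line term gives such signs, so they are not evidence apart from that term. Leaving out 1 sample gave 38 clones (without the 2nd 4E sample) to 85 for heavy basal. It gave 52 (without the 1st NIH 3T3 sample) to 397 (without the 1st 4E sample) for heavy starved. In the light fraction it gave 1 (without the 2nd 4E sample) to 48 for light basal, and 38 (without the 1st NIH 3T3 sample) to 105 for light starved.

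Averaged over fraction and serum, 397 clones differed between the cell lines (191 positive, 206 negative). Clone H3073H04 stood at 3.30 ± 0.26 in the 8 4E samples and at 0.03 ± 0.55 in the 8 NIH 3T3 samples, a difference of 3.28 (SE 0.16, adjusted p = 8.21e-08). Clone H3058D02 differed by 2.90 (SE 0.18, adjusted p = 1.25e-06). Clone H3143B04 stood at -1.88 ± 1.20 in the 4E and at 1.69 ± 0.55 in the NIH 3T3 samples, a difference of -3.57 (SE 0.27, adjusted p = 5.98e-06). Clone H3151B02 differed by -2.42 (SE 0.22, adjusted p = 4.07e-05). For all 4 of these clones the samples of the cell lines did not overlap. This average was added after the data were seen, because it is balanced over a technical split of the samples described with the cell line by serum term.

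Each comparison of starved with basal samples in 1 line and fraction crosses the technical split described with the cell line by serum term. Starvation and the split cannot be told apart in it. In the fit of all 8 groups, starved and basal samples differed at 36 clones in the heavy fraction of NIH 3T3 (20 positive, 16 negative as starved minus basal). In that of NIH 3T3/4E they differed at 320 (216 positive, 104 negative). In the light fraction 8 clones passed in NIH 3T3 (2 positive, 6 negative) and 24 in NIH 3T3/4E (13 positive, 11 negative). When only the 2 groups compared were fitted, the counts were 0 (heavy NIH 3T3), 71 (heavy 4E), 0 (light NIH 3T3) and 0 (light 4E), and with the replicate number as a block heavy NIH 3T3 gave 18. With quantile normalization the heavy NIH 3T3 split became 18 positive and 23 negative, and that of light 4E 13 positive and 16 negative. The heavy 4E count was 211 with quantile normalization, 122 with scaling to 1 median absolute deviation and 103 with array weights. In heavy NIH 3T3 samples, clone H3111E04 differed by 3.90 (SE 0.60, adjusted p = 0.0157) and clone H3106E08 by 3.41 (SE 0.61, adjusted p = 0.0338). The 2 basal samples of clone H3106E08 stood far apart (mean -1.06, SD 1.91), and its SE comes from the fit of all 8 groups. Clone H3076B11 differed by -3.30 (SE 0.41, adjusted p = 0.0069) and clone H3105C02 by -2.94 (SE 0.46, adjusted p = 0.0157). In heavy 4E samples, clone H3123F12 differed by 3.99 (SE 0.86, adjusted p = 0.0303) and clone H3109F04 by 3.97 (SE 0.34, adjusted p = 0.000119). Clone H3106B10 differed by -3.64 (SE 0.65, adjusted p = 0.0171) and clone H3152B02 by -3.13 (SE 0.47, adjusted p = 0.00773). In light samples, clone H3108G06 (2.87) and clone H3012B03 (-3.77) had the largest differences in NIH 3T3, and clone H3157G08 (3.19) and clone H3154E06 (-3.82) in NIH 3T3/4E. Heavy and light responses of 1 cell line went together across clones, with r of 0.46 in each line. The responses of the 2 lines did not, with r of -0.16 in the heavy and -0.12 in the light fraction. Among the 3018 clones with unequal columns in every sample these turned to 0.089 and 0.099. Of the 16 clones that passed in the heavy fraction of both lines 14 had opposite signs. A cell line by serum term larger than the serum term gives such signs, so they are not evidence apart from that term. Leaving out 1 sample gave 8 (without the 1st starved sample) to 84 (without the 2nd basal sample) clones for heavy NIH 3T3 and 37 (without the 2nd basal sample) to 671 (without the 1st starved sample) for heavy 4E. In the light fraction it gave 8 to 46 (without the 2nd starved sample) for light NIH 3T3, and 9 (without the 2nd basal sample) to 61 (without the 1st basal sample) for light 4E.

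Averaged over cell line and fraction, an average also added after the data were seen, 449 clones differed between starved and basal cells (266 positive, 183 negative). With quantile normalization the split was 202 positive and 203 negative. Clone H3128D02 stood at 1.59 ± 0.59 in the 8 starved and at -1.09 ± 0.46 in the 8 basal samples, a difference of 2.68 (SE 0.25, adjusted p = 0.000216). Clone H3124H10 differed by 2.15 (SE 0.32, adjusted p = 0.00353). Clone H3019C03 differed by -1.92 (SE 0.21, adjusted p = 0.000715) and clone H3154E06 by -1.90 (SE 0.23, adjusted p = 0.000902). Starved and basal samples overlapped for these 2 clones but not for the 2 positive ones. From basal to starved, the group means of clone H3154E06 went from -1.60 to -3.78 in 4E heavy and from 0.12 to -3.69 in 4E light samples. In NIH 3T3 they went from -0.99 to -1.46 (heavy) and from 0.42 to -0.72 (light). The count was 231 without the 1st sample of NIH 3T3 heavy basal and 640 without the 1st sample of 4E heavy starved.

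**Figure D3:**
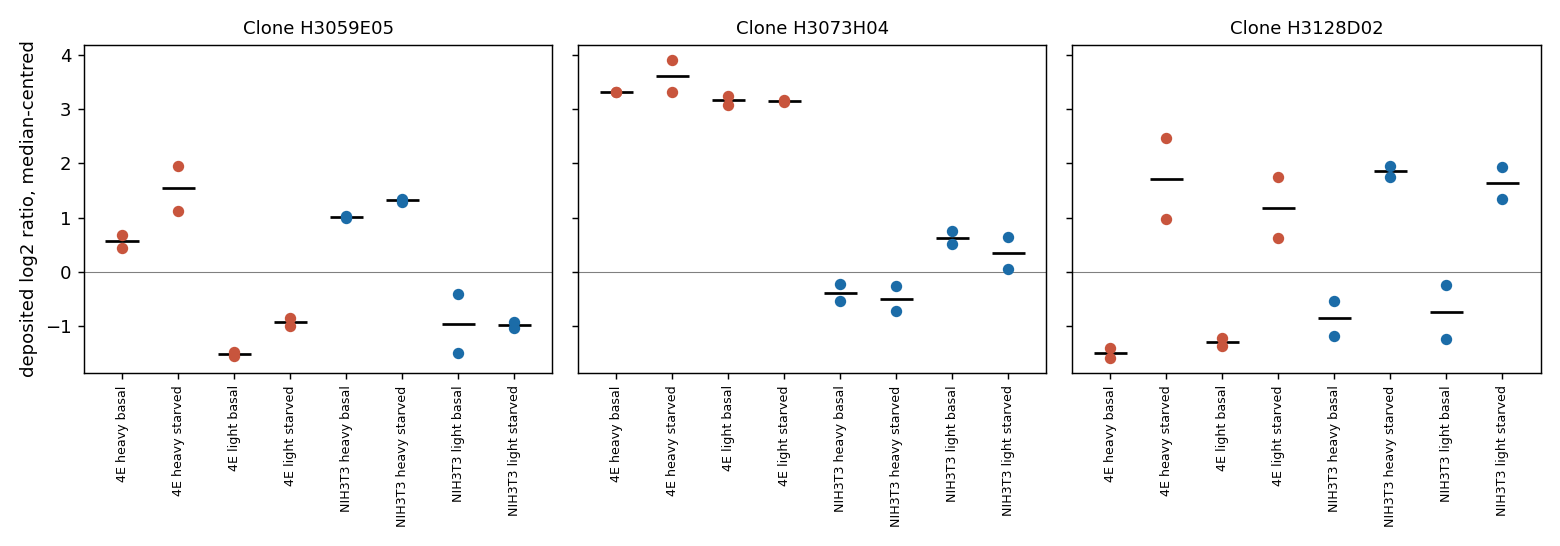
Median-centred deposited log2 ratio of 3 clones in each sample (points, red for NIH 3T3/4E and blue for NIH 3T3) with the mean of the 2 samples of each group (black lines). Clone H3059E05 separates heavy from light samples, clone H3073H04 the 8 4E samples from the 8 NIH 3T3 samples, and clone H3128D02 starved from basal samples.

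A change in the share of a transcript on heavy polysomes, relative to other clones, would appear as a difference between heavy minus light values of 2 states. Each sample was centred on its median, so a move of most transcripts between the fractions could not be seen here. No clone passed for the cell line by fraction term by limma, in basal cells (621 at an unadjusted p under 0.05, 4.09% of the clones) or in starved cells (669, 4.41%). None passed for serum by fraction in NIH 3T3 (525, 3.46%) or in NIH 3T3/4E (793, 5.23%), or for the term of all 3 factors (841, 5.54%). Clone H3009C04 came nearest in starved cells, with a difference of -3.69 (SE 0.53, adjusted p = 0.08), and clone H3110C07 for the term of all 3 factors, at -4.33 (SE 0.66, adjusted p = 0.16). The median 95% half-width was 1.19 log2 units for the cell line by fraction and serum by fraction terms and 1.68 for the term of all 3 factors, both without adjustment for the number of clones. The adjusted test reaches less far with 2 samples per group. In simulated data it found 15.1% of shifts of 2 log2 units and 68.7% of shifts of 3 units for cell line by fraction in basal cells, and 0.2% and 3.7% for the term of all 3 factors. Leaving out 1 sample gave up to 29 clones, the most for cell line by fraction in basal cells without the 2nd sample of NIH 3T3 heavy basal.

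The response to starvation differed between the cell lines at 263 clones in the heavy fraction (151 positive, 112 negative as the 4E minus the NIH 3T3 response). In the light fraction it differed at 160 (94 positive, 66 negative). Fits of only the groups compared, with fewer degrees of freedom, gave 99 (heavy) and 96 (light) clones. In the heavy fraction clone H3111G01 differed by 6.07 (SE 1.11, adjusted p = 0.0125) and clone H3152A09 by 5.96 (SE 0.86, adjusted p = 0.00316). Clone H3111E04 differed by -6.55 (SE 0.85, adjusted p = 0.00154) and clone H3106B10 by -6.42 (SE 0.92, adjusted p = 0.00316). In the light fraction clone H3012B03 differed by 5.88 (SE 0.85, adjusted p = 0.00427) and clone H3106E06 by 5.28 (SE 0.59, adjusted p = 0.00171). Clone H3152B02 differed by -4.96 (SE 0.66, adjusted p = 0.00245) and clone H3109H04 by -4.73 (SE 0.97, adjusted p = 0.0308). All 54 clones that passed in both fractions had the same sign (2.77 in both by chance), and the heavy and light differences correlated across clones at r = 0.45. The 2 control rows held values in the 8 samples of NIH 3T3 basal and 4E starved and were empty in the 8 samples of NIH 3T3 starved and 4E basal. That split coincides with the cell line by serum term, so the term and the split cannot be told apart. Each comparison of 2 single groups by cell line or by serum crosses the split too. Within the sides of the split, 477 clones differed between 4E starved and NIH 3T3 basal cells and 368 between 4E basal and NIH 3T3 starved cells, comparisons in which cell line and serum change together. The first fell to 305 without the 2nd sample of NIH 3T3 light basal, and the second to 165 without the 1st sample of NIH 3T3 heavy starved. Across clones the first and the second correlated at r = 0.02. Of the 71 clones that passed in both, 48 had the same sign and 23 opposite signs. Serum changes in opposite directions in these comparisons. Heavy and light samples differed at 1563 clones within the side with control values and at 982 within the other, with r = 0.61 across clones between the sides. With 1 sample left out the counts were 552 (without the 2nd sample of NIH 3T3 light basal) to 1876 for the first and 266 (without the 2nd sample of NIH 3T3 light starved) to 999 for the second. Leaving out 1 sample gave 97 (without the 1st sample of NIH 3T3 heavy starved) to 422 (without the 1st sample of 4E heavy starved) clones for the heavy and 62 (without the 1st sample of NIH 3T3 light starved) to 128 for the light fraction.

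**Figure D4:**
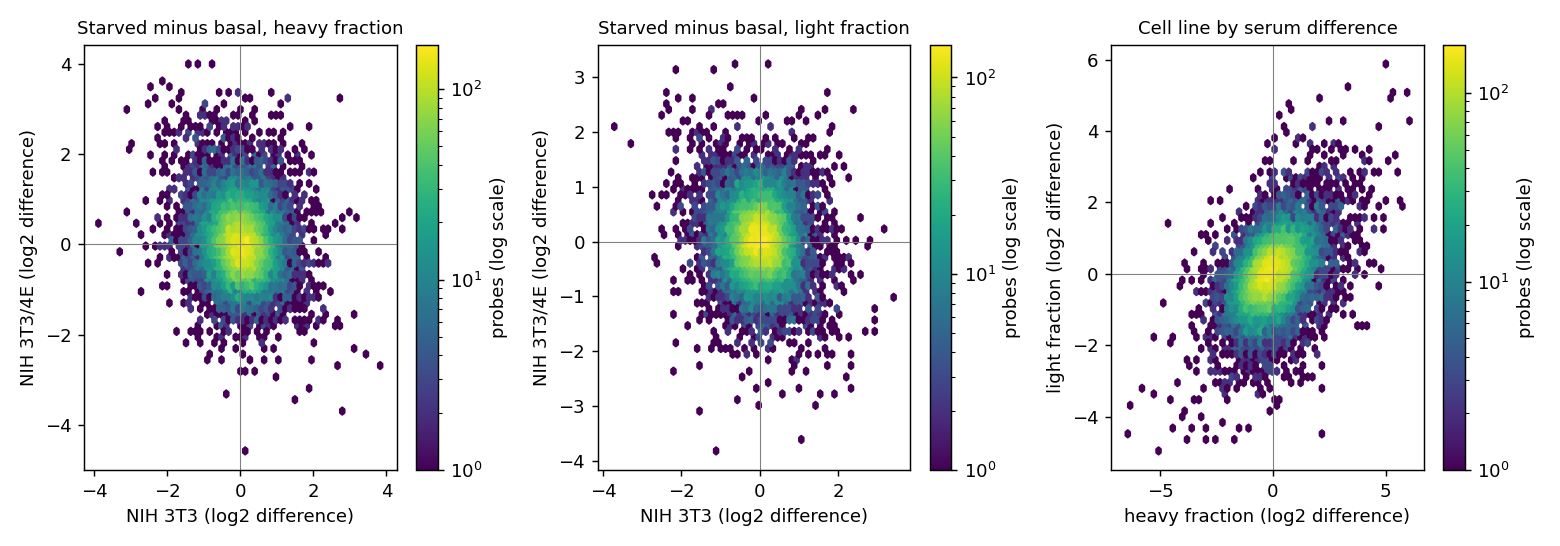
Differences of all 15169 clones (hexagons shaded by the number of clones on a log scale, axes in log2 units): starved minus basal in NIH 3T3 against NIH 3T3/4E for each fraction, and the cell line by serum difference in the heavy against the light fraction. The responses of the lines correlate at -0.16 and -0.12 (0.089 and 0.099 among the 3018 clones with unequal columns in every sample), and the cell line by serum differences of the fractions at 0.45.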

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

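The test on the control rows was chosen only after the result was seen; the tests on print plates, on a single sample and on other splits of the samples were chosen before. The starvation response differed between the cell lines by a test of the difference itself, at 263 clones in the heavy and 160 in the light fraction. Fits of only the groups compared gave 99 and 96. For print plates that differed between array lots, the prediction was a correlation between the heavy and the light differences under 0.1 after removing plate medians. It was 0.44 after removal and 0.45 before. Plates held 4.15% (heavy) and 4.97% (light) of the variance of these differences, so removal could hardly have lowered it that far. The values show that shifts of whole plates carried little of the correlation. Differences between lots within a plate were not tested. A single deviant sample cannot give a difference in both fractions, which share no sample. The correlation was 0.47 without the 2nd sample of 4E heavy starved, but for that reason it could hardly have fallen under 0.1. It was 0.33 or more with the heavy and light samples of any 1 state and number left out together (chosen after seeing the data). The numbers need not mark 1 culture, so a deviant culture that gave both a heavy and a light sample is not excluded. The counts of clones fell without some single samples. An array or processing batch marked by the control rows stays open: the cell line by serum mean square was 2.73 times that between replicates, and no group has samples on both sides of the split. A response to starvation that depends on eIF4E stays open for the same reason and was not tested apart from the batch.

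Chance was tested for the 3 averages over 8 against 8 samples by relabelling within strata. For heavy against light, 1 of 100 splits, the real one with 2743 clones, gave as many, and the highest other gave 769. For the cell lines 1 of 100 did, the real one with 397 clones against a highest other of 192, and for starvation 1 of 100, with 449 clones against 46. The smallest share that 100 splits can give is 1 in 100, so for heavy against light chance is made unlikely but is not excluded. In each stratum of the cell line and starvation averages, the factor relabelled coincides with the split that follows the control rows. Relabelled groups therefore mix the sides of that split, which can raise their spread and lower their counts. For these averages the share of 1 in 100 does not by itself measure chance. The split that follows the control rows was not among those drawn, and it gives 710 clones, more than the cell line or the starvation average.

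The control rows lie outside the comparisons. In the 8 samples that hold them, the higher and the lower column differed by a median of 2.91 log2 units for the buffer row. For the Arabidopsis row the median was 3.35. The columns had opposite signs in 8 of these samples for the buffer row and in 7 for the Arabidopsis row, so the values need not be signal. Clones with unequal columns had a median gap of 0.20 in the middle sample, which is a median over many clones where each control is 1 row.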

How the results depend on the processing

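The settings chosen only after the data were seen were the single columns of a pair, the clones with unequal columns in every sample, the removal of plate medians and the pairing of heavy with light samples within a state. Counts of clones past the threshold are given where they moved by over 1.5 times, and the cause was not tested unless a cause is named. All 18 counts stayed within 1.5 times without centring, with the wider filter on missing values, with robust moderation and with plate medians removed. The filter that asks for all 32 columns removes no further clone, and the averages per gene, the gene lists and the turned signs were not run. Heavy against light and both averages added after the data were seen stayed within 1.5 times under every setting that kept all samples as units and all clones.

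With the replicate number as a block, the count fell from 68 to 45 for 4E against NIH 3T3 in heavy basal samples, from 146 to 84 in light starved samples. It fell from 36 to 18 for starvation in heavy NIH 3T3 samples, and the other 15 stayed within 1.5 times. Whether the numbers pair the samples is not settled. Replicate differences of the heavy and light samples of a state correlated across clones at -0.33 in NIH 3T3 basal and 0.36 in NIH 3T3 starved. In 4E basal and 4E starved the values were 0.21 and 0.01. With heavy and light samples of 1 state paired as a block, heavy against light gave 2708 clones and the 5 terms that involve fraction stayed at 0.

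With each of the 32 columns as a replicate, as the earlier design had it, the columns of a pair pass for separate samples and every count rose. For 4E against NIH 3T3 it gave 3031 (heavy basal), 3816 (heavy starved), 1954 (light basal), 3199 (light starved) and 3551 (average). For starvation it gave 2773 (heavy NIH 3T3), 4326 (heavy 4E), 2145 (light NIH 3T3), 2835 (light 4E) and 3815 (average). Heavy against light gave 6107. For cell line by fraction it gave 607 (basal) and 714 (starved), for serum by fraction 438 (NIH 3T3) and 921 (4E), for cell line by serum 4036 (heavy) and 2651 (light), and for all 3 factors 1018. With the title number as a replicate block in that fit, the counts in the same order were 2902, 3695, 1866, 3046 and 3437, then 2647, 4211, 2036, 2745, 3671 and 6048, then 537, 655, 421, 890, 3880, 2598 and 917.

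Fits of only the groups compared have fewer degrees of freedom. They gave 2, 12, 0 and 0 clones for 4E against NIH 3T3 (heavy basal, heavy starved, light basal, light starved), 0, 71, 0 and 0 for starvation (heavy NIH 3T3, heavy 4E, light NIH 3T3, light 4E). For cell line by serum they gave 99 (heavy) and 96 (light). Quantile normalization gave 127 (4E against NIH 3T3, heavy basal), 56 (light basal), 211 (starvation, heavy 4E), 30 (light NIH 3T3), 1 (cell line by fraction, starved) and 1 (serum by fraction, NIH 3T3). Scaling to 1 median absolute deviation gave 87 (4E against NIH 3T3, heavy starved), 116 (light basal), 88 (light starved), 122 (starvation, heavy 4E), 19 (light NIH 3T3) and 46 (light 4E). Array weights gave 162 (4E against NIH 3T3, heavy basal), 63 (heavy starved), 67 (light basal), 103 (starvation, heavy 4E) and 53 (light 4E). These weights were equal for both samples of a group, 0.63 for each in 4E heavy starved, so they set groups and not single samples apart. The lower column of each pair gave 45 (4E against NIH 3T3, heavy basal), 12 (starvation, heavy NIH 3T3), 204 (heavy 4E), 4 (light NIH 3T3) and 1 (serum by fraction, 4E), and the higher column 14 (starvation, light NIH 3T3).

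The 3018 clones with unequal columns in every sample are fewer clones tested. They gave 26, 54, 1 and 47 for 4E against NIH 3T3 (heavy basal, heavy starved, light basal, light starved) and 210 for its average. They gave 1, 116, 0 and 8 for starvation (heavy NIH 3T3, heavy 4E, light NIH 3T3, light 4E). They gave 1513 for heavy against light, and 34 and 32 for cell line by serum (heavy, light). In them the correlations that were negative over all clones turned positive, to 0.089 (heavy) and 0.099 (light) between the starvation responses of the lines, and to 0.056 (heavy) and 0.14 (light) between the basal and starved cell line differences.

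Leaving out 1 sample leaves its group with a lone sample, assumed to vary like the other groups. For 4E against NIH 3T3 the ranges were 38 to 85 (heavy basal), 52 to 397 (heavy starved), 1 to 48 (light basal), 38 to 105 (light starved) and 273 to 452 (average). For starvation they were 8 to 84 (heavy NIH 3T3), 37 to 671 (heavy 4E), 8 to 46 (light NIH 3T3), 9 to 61 (light 4E) and 231 to 640 (average). Heavy against light gave 2197 to 2974. They were 0 to 29 and 0 to 10 for cell line by fraction (basal, starved), 0 to 27 and 0 to 12 for serum by fraction (NIH 3T3, 4E), 97 to 422 and 62 to 128 for cell line by serum (heavy, light), and 0 to 5 for all 3 factors. No clone named by the rule reversed its sign under any of these settings. Those with a call lost it in 48 of 384 values without 1 sample and in 22 of 40 from fits of only the groups compared. Of 52 values each, they lost it in 3 with the lower column, in 2 each with array weights, quantile normalization and scaling to 1 median absolute deviation, and in 1 with the replicate block. They kept it in all values of the other settings.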

Other observations

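The test in the first paragraph was chosen only after the result was seen. Clones differed in how often both columns of a sample held 1 value. Of the 3018 clones with unequal columns in every sample, 42.8% passed for heavy against light, against 13.3% of the 10175 clones with equal columns in 1 to 4 samples and 4.81% of the 1976 with equal columns in 5 or more. The fraction mean square over that between replicates was 9.21, 3.31 and 1.62 in these 3 classes, that of the cell line 3.17, 2.04 and 1.36, and that of serum 3.30, 1.94 and 1.23. The cell line by serum mean square did not weaken in this way, at 2.30, 2.91 and 2.53, a ratio of 1.10 between the last and the first class, where the ratios of the other terms were 0.18, 0.43 and 0.37. The correlation between its heavy and light differences fell, from 0.52 to 0.45 and 0.38, and the clones past the threshold made up 1.36, 1.86 and 1.67% in the heavy and 1.06, 1.12 and 0.71% in the light fraction. The median residual SD was 0.40, 0.39 and 0.41 in the 3 classes, so the classes did not differ in this way in replicate spread. What equal columns stand for is not given in the sources used here, and the design ties the control row split to the cell line by serum term, so the ratio does not decide between a batch and a biological response.

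The negative correlation between the starvation responses of the lines was not seen in the clones with unequal columns in every sample. It was -0.22 in the heavy fraction for clones with equal columns in 1 to 4 samples and -0.27 for those with 5 or more, and 0.09 for those with none. Its sign depends on whether the serum or the cell line by serum term is larger. Their mean square ratios were 3.30 and 2.30 with none, 1.94 and 2.91 with 1 to 4, 1.23 and 2.53 with 5 or more. The correlation therefore restates these terms and is not a separate result. Of the 51 clones named by the rule, 35 had equal columns in at least 1 sample, with a median of 1 such sample against 2 for all clones. Clones H3073H04, H3143B04 and H3059E05 had unequal columns in every sample.

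Differences between clones followed the plate part of the clone ID to a small extent. Plates held 4.15% of the variance of the cell line by serum difference in the heavy and 4.97% in the light fraction, 3.30% for heavy against light, 2.34% for the cell line average and 2.32% for the starvation average, against at most 1.36% in 100 shuffles of the clones.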
